A study of Homo sapiens with 6 samples.

How the data were processed

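RNA from 3 untreated LNCaP libraries and 3 libraries of cells given a cumulative 40 Gy of FIR was sequenced, and 1 table of 16311 genes covers all 6. The authors deposited raw read counts per gene and library, per the file headers. The same table gives the authors' log2 fold changes, log2 CPM and log2 RPKM values and their p-values with adjusted p-values, per the file headers. The submitters' processing notes name bcl2fastq, STAR 2.5, featureCounts, Subread 1.6.2, edgeR 3.20.8 and the hg38 build, with no role or setting. The annotation release, the strand setting, the treatment of reads that map to several places and the filter on low genes are not given in the sources used here. Antisense and overlapping genes may therefore share reads, and so may near-identical copies. Every gene reached 0.6 CPM in at least 3 libraries, so low genes had been removed from the deposited counts. A scarce gene could enter through the group where it was higher. Counts of measured list members leave out genes that were low in both groups.

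All results come from the counts. Each column was matched to its sample by name, and 0 columns of sample values were left unmapped. Counts were scaled by TMM factors and fitted in edgeR 4.0.16 under R 4.3.3 with glmQLFit and glmQLFTest, with the group as the only term, and p-values were adjusted over all 16311 genes by Benjamini-Hochberg with a threshold of 0.05. The filterByExpr rule with a minimum count of 10 removed no gene. SE is the log2 fold change divided by the square root of F, and CPM values are given as mean ± SD over 3 libraries. The 95% counting intervals of the KCNC2 and SALL4 ratios, the counting bounds of PIF1 and NEIL3 and the floor of 3 reads over a group cover counting error only. The 95% bounds of single log2 fold changes come from the edgeR fit and include the spread between libraries, and the 95% intervals of medians over genes and of rho are bootstraps over genes, which are not independent replicates. No spike-in was used here, so changes are relative to the other genes.

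The authors' deposited table calls 4249 genes higher and 3901 lower at the same threshold, and 7879 of those 8150 were also called here. The log2 fold changes of both had a Pearson r of 1.000 across genes, which are not independent replicates.

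Before the data were examined, 26 gene lists with 815 entries were written, of which 610 entries matched a tested gene. Lists with at least 5 tested members were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the lists. With an estimated correlation 0 lists passed. Also fixed in advance was the rule for the genes to name: the 6 largest rises and 6 largest falls among called protein-coding genes with a mean of at least 5 CPM and no overlap between groups; KLK3, ENO2, CHGA, SYP, REST, CDKN1A, PRMT5 and 1 more gene that is not reported here; and, from each list, the 2 called members of largest change with a mean of at least 1 CPM, or the most abundant member if none was called. Other genes named were chosen after their values were seen.

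GENCODE release 29 gave a biotype for 15937 of the genes by identifier. In all, 183 rows lay off the primary chromosomes, on alternate haplotypes or unplaced sequences, and 72 symbols stood on more than 1 row (156 rows). A list member with several rows was taken from the primary chromosomes where it had one there. The pipeline was tested on simulated counts for 15973 genes of this comparison. There edgeR recovered 75.3% of 93 genes changed 2-fold and 98.9% of 95 changed 4-fold, and 9 of 173 calls were false. Far fewer genes were changed in the simulation than were called in the data, so these rates need not hold for the data.

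Alternatives were RLE, upper-quartile and library-size scaling, DESeq2 1.42.0, limma-voom, no filter, a filter of 1 CPM in 3 libraries, the replicate number as a block, each library left out in turn, and camera with an estimated correlation. Rows sharing a symbol were also summed, an alternative chosen after seeing the data. No pair of libraries in a group differed by as little as sampling noise, so none looked like a repeat sequencing of another. Each was counted as 1 replicate, though this does not show that the cultures were separate.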

Results

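Gene expression was measured by RNA sequencing in LNCaP, an established human cell line of androgen-sensitive prostate adenocarcinoma. The table held 6 libraries, 3 from untreated cells and 3 from cells given a cumulative dose of 40 Gy, which the labels call FIR without spelling it out and the series title ties to radiation. Read totals over the 16311 listed genes were 18928571, 21004697 and 16805679 in the untreated libraries and 16542096, 15703483 and 16356183 in the FIR libraries. At these depths 3 reads correspond to between 0.143 and 0.191 CPM, a gene's reads scaled to a fixed library total. The labels number the replicates 1 to 3 in each group but do not say how the cultures were separated, so the p-values measure the spread between these libraries, which may be technical. Spearman correlations of the libraries across genes were 0.990 to 0.994 within a group and 0.937 to 0.945 between groups. Positions are on hg38 and fold changes are FIR over untreated.

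The comparison asked which genes differ between LNCaP cells that received the cumulative dose and cells that did not, and, from the series title, whether neuroendocrine-like expression is among the differences. Of 41 measured genes of G2/M and mitosis all fell, and of 32 measured p53 target genes 28 rose, 1 fell and 3 did not pass. Camera tests a list against all other genes. It called the mitosis list lower and the p53 list higher (adjusted p = 1.9e-28 and 5.4e-12). Neither call was kept with an estimated correlation (adjusted p = 0.196 for each with an estimated correlation), where 0 lists passed. CDKN1A, the cyclin-dependent kinase inhibitor p21 (ENSG00000124762.13, chromosome 6, 36676460 to 36687339), went from 292 ± 6.73 to 2352 ± 410 CPM (SD, n = 3), 8.05 times higher. SYT4, a synaptotagmin of secretory vesicles, went from 37.9 ± 6.06 to 1694 ± 118 CPM (SD, n = 3), 44.8 times higher. BIRC5, which encodes the mitotic protein survivin, went from 124 ± 29.6 to 0.459 ± 0.187 CPM (SD, n = 3). With edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment, 7947 of 16311 genes passed an adjusted p of 0.05, 4136 of them higher and 3811 lower in FIR cells. Of these, 1406 were at least 2 times higher and 1202 at least 2 times lower. In 56.9% of genes the FIR and untreated libraries did not overlap, where chance gives 10%.

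**Figure D1:**
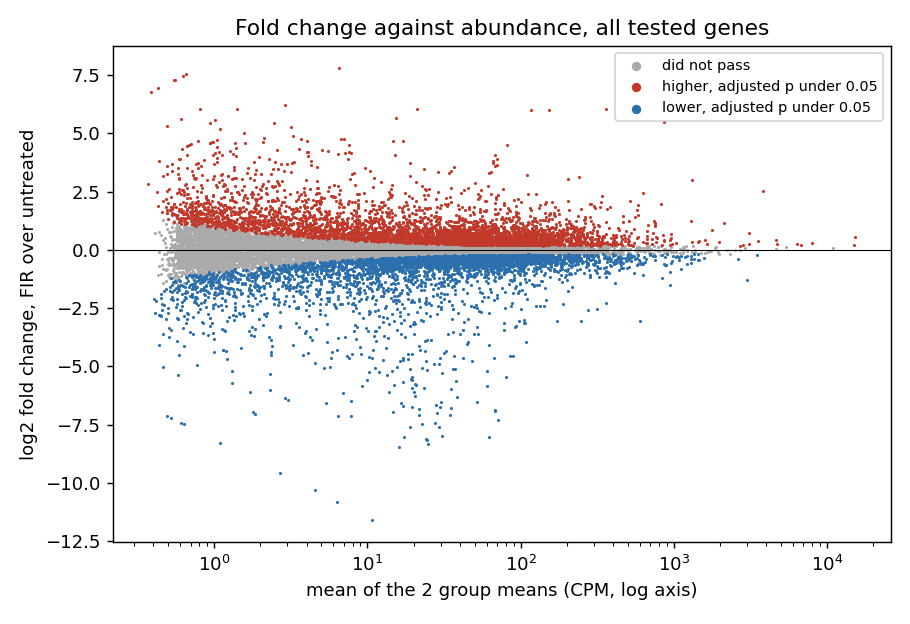
Each point is 1 of the 16311 genes, with its mean CPM on a log axis and its fitted log2 fold change, FIR over untreated; red and blue mark the 4136 higher and 3811 lower genes. The falls reach further than the rises, and the lowest fitted values belong to genes with 0 reads in FIR cells, such as PIF1, whose fitted fold is not a bound.

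The 6 largest rises under the rule for named genes were those of KCNC2, ADRA2A, GRIN3A, IGFBP3, SYT4 and NRG3. KCNC2, a voltage-gated potassium channel subunit, had 3 reads over the untreated group and 614 over the FIR group, a ratio of 248 with a 95% counting interval of 84.6 to 1207. ADRA2A, an alpha-2 adrenergic receptor, rose from 10.9 ± 1.56 to 707 ± 111 CPM (SD, n = 3), and GRIN3A, an NMDA receptor subunit, from 3.47 ± 1.86 to 230 ± 18.1 CPM. NRG3, a neuregulin, rose by a log2 fold change of 4.74 (SE 0.26). IGFBP3, an insulin-like growth factor binding protein, rose by 5.98 (SE 0.62), but its FIR libraries stood at 406, 52.9 and 448 CPM against 2.74 to 6.36 CPM in untreated cells. The 6 largest falls under that rule were those of PIF1, NEIL3, CEP55, KIF18B, DLGAP5 and NCAPG. PIF1, a DNA helicase, and NEIL3, a DNA glycosylase, had 0 reads in all FIR libraries. They were 345-fold and 202-fold lower against a floor of 3 reads over the group, with lower 95% counting bounds of 280 and 164. CEP55, KIF18B, DLGAP5 and NCAPG, which act in mitosis and cytokinesis, had log2 fold changes of -8.45, -8.34, -8.13 and -8.11. Adjusted p-values of these genes ran from 1.8e-13 for SYT4 to 1.4e-06 for IGFBP3.

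Genes of the androgen axis moved in both directions. KLK3, which encodes prostate-specific antigen (chromosome 19, 50854915 to 50860764), fell by 0.37 (SE 0.08, adjusted p = 9.0e-04), from 2958 ± 163 to 2282 ± 197 CPM (SD, n = 3). Among 31 measured androgen-responsive genes, 17 rose, 10 fell and 4 did not pass, with the same counts adjusted over the list alone. ACPP, prostatic acid phosphatase, rose by 3.04 (SE 0.14) and the cation channel TRPM8 by 2.28 (SE 0.17), while HPGD, which degrades prostaglandins, fell by 2.18. The list as a whole did not pass camera (adjusted p = 0.134). PRMT5, an arginine methyltransferase, fell by 0.55 (SE 0.08, adjusted p = 4.0e-05).

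Neuroendocrine markers divided. Of 38 listed markers 12 were measured, and 5 rose, 0 fell and 7 did not pass, with the same counts adjusted over the list alone. SYT4 and RTN1, a reticulon of neuroendocrine cells, rose by 5.49 (SE 0.12) and 3.58 (SE 0.13), and CPE rose by 0.35 (SE 0.10). UCHL1 and PEG10 also rose, by 2.14 (SE 0.45) and 1.35 (SE 0.40), but both were scarce. UCHL1 went from 0.335 to 1.48 CPM and PEG10 from 0.687 to 1.77 CPM. ENO2, neuron-specific enolase, had a log2 fold change of 0.31 (SE 0.20, adjusted p = 0.217), and SYP, synaptophysin, 0.17 (SE 0.20, adjusted p = 0.510). Without untreated replicate 3, ENO2 stood at 0.52 with an adjusted p of 0.030. CHGA, chromogranin A, had no row in the table, so it is not analysed here. Low genes had been removed, so CHGA and other markers without a row may have been too scarce, which cannot be checked here. The 5 rises are a count among measured markers only. The list was higher by camera (adjusted p = 0.040), which was not kept with an estimated correlation (adjusted p = 0.221 with an estimated correlation), without FIR_40Gy replicate 2 (adjusted p = 0.065) or with a filter of 1 CPM in 3 libraries (adjusted p = 0.063).

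Of 44 listed genes of the neuronal cytoskeleton, axon and synapse 23 were measured. Among these 15 rose, 5 fell and 3 did not pass, with the same counts adjusted over the list alone. The axon guidance receptor EPHA5 rose by 4.23 (SE 0.44), from 0.122 to 2.41 CPM, the synapsin SYN2 by 2.75 (SE 0.38), and the dendritic protein MAP2 by 2.08. EPHA5 reached 0.6 CPM in the FIR libraries only. DPYSL3, a protein of growth cones, fell by 2.05. The list median was 1.02 and camera called it higher (adjusted p = 0.0094), not kept with an estimated correlation (adjusted p = 0.226 with an estimated correlation). REST, a repressor of neuronal genes, had a log2 fold change of 0.21 (SE 0.08, adjusted p = 0.048), a call lost under 10 of the alternatives with adjusted p up to 0.181.

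**Figure D2:**
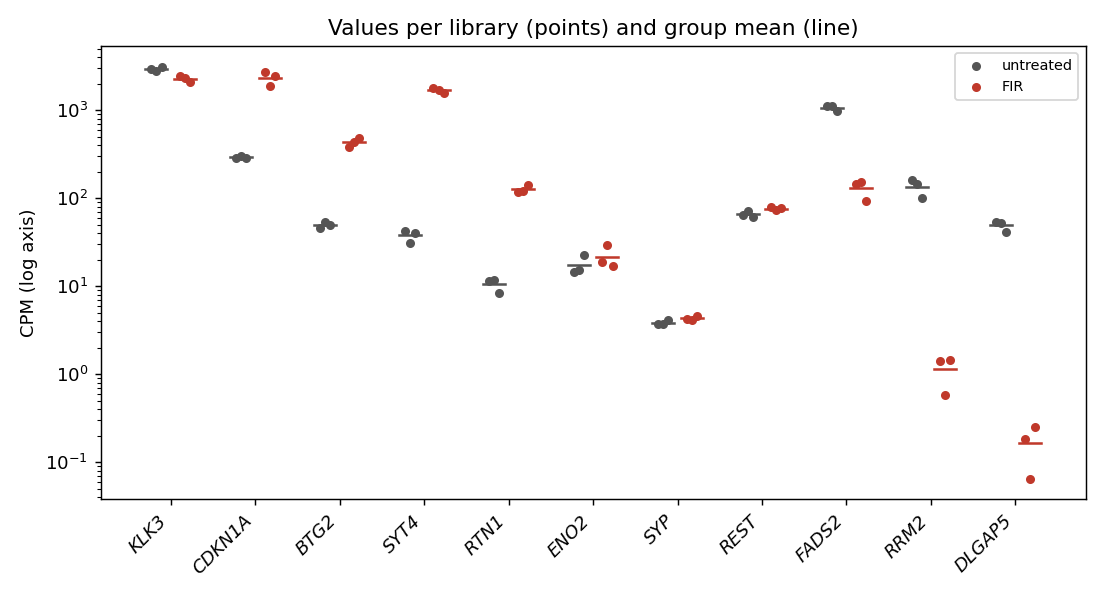
Points give CPM per library on a log axis for 11 genes in untreated (grey) and FIR (red) cells, and lines give the mean of 3 libraries. SYT4 rose from a mean of 37.9 to 1694 CPM, while the ENO2 libraries of the groups overlap.

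Of 32 measured p53 target genes 28 rose, 1 fell and 3 did not pass; 29 rose adjusted over the list alone. BTG2, an antiproliferative gene, rose by 3.12 (SE 0.10) and CDKN1A by 3.01 (SE 0.11). MDM2, the ubiquitin ligase of p53, rose by 1.83 and the death receptor FAS by 2.29, while PMAIP1 had a log2 fold change of -0.03 that did not pass. The list was higher by camera (adjusted p = 5.4e-12), not kept with an estimated correlation (adjusted p = 0.196 with an estimated correlation).

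All 41 measured genes of G1/S and DNA replication and all 41 of G2/M and mitosis fell, also adjusted over the list alone. MCM10, a replication initiation factor, fell by 7.45 (SE 0.36) and RRM2, a ribonucleotide reductase subunit, fell by 6.87 (SE 0.23). MKI67, the proliferation marker, fell by 5.43 and the mitotic kinase CDK1 fell by 4.55. List medians were -2.39 and -5.19. Camera called both lower (adjusted p = 6.8e-23 and 1.9e-28), not kept with an estimated correlation (adjusted p = 0.221 and 0.196 with an estimated correlation).

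Of 38 measured genes of homologous recombination and the Fanconi pathway 32 fell, 1 rose and 5 did not pass; 2 rose adjusted over the list alone. The nuclease EXO1 fell by 5.58 (SE 0.30) and the helicase BLM fell by 5.03 (SE 0.32). Of 16 measured genes of non-homologous end joining 10 fell, 0 rose and 6 did not pass, the same adjusted over the list alone, with PAXX and MAD2L2 lowest at -0.91 (SE 0.10) and -0.71 (SE 0.09). Camera called both lists lower (adjusted p = 3.5e-13 and 0.0023), not kept with an estimated correlation (adjusted p = 0.221 and 0.196 with an estimated correlation).

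Replication-dependent histone genes did not follow the replication genes. Of 16 measured members 13 rose and 3 fell, the same adjusted over the list alone. HIST1H2BF rose by 2.14 (SE 0.21), from 2.45 to 10.8 CPM, while HIST1H2AG fell by 2.11 (SE 0.20), from 10.4 to 2.41 CPM. These genes have near-identical copies, so the value of each single one is uncertain. Camera called the list higher (adjusted p = 5.6e-04), not kept with an estimated correlation (adjusted p = 0.196 with an estimated correlation).

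Immune-related lists held rises and falls. Of 35 measured interferon-stimulated genes 17 rose, 3 fell and 15 did not pass, the same adjusted over the list alone. TRIM22, an antiviral ubiquitin ligase, rose by 4.67 (SE 0.21) and LGALS3BP by 2.37 (SE 0.13), while OAS3, an oligoadenylate synthetase, fell by 2.16. That list was higher by camera (adjusted p = 0.040), not kept with an estimated correlation (adjusted p = 0.289 with an estimated correlation) or without FIR_40Gy replicate 2 (adjusted p = 0.065). Of 11 measured genes of MHC class I presentation 7 rose, 1 fell and 3 did not pass (camera adjusted p = 0.057). HLA-B rose by 1.35 (SE 0.28) and the peptidase ERAP2 by 1.29 (SE 0.27). That HLA-B value comes from 1 of 4 rows on alternate haplotype sequences, at 1.65 and 4.18 CPM. Of 11 measured NF-kappaB and secreted inflammatory genes 5 rose, 3 fell and 3 did not pass (camera adjusted p = 0.187), with the cytokine LIF up by 2.59 (SE 0.12). Counts of the last 2 lists were the same adjusted over the list alone.

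Of 32 measured genes of cholesterol and fatty acid synthesis 23 fell, 2 rose and 7 did not pass, and the desaturases FADS1 and FADS2, neighbours on chromosome 11 whose annotated spans overlap, stood at -3.12 (SE 0.10) and -3.03 (SE 0.15). Of 29 measured genes of the unfolded protein and ATF4 responses 19 fell, 6 rose and 4 did not pass, with CHAC1, which degrades glutathione, and PHGDH, of serine synthesis, at -2.31 (SE 0.17) and -2.30 (SE 0.09). Camera called both lists lower (adjusted p = 6.7e-06 and 0.0016), not kept with an estimated correlation (adjusted p = 0.226 and 0.327 with an estimated correlation). Of 24 measured NRF2 genes 8 fell, 4 rose and 12 did not pass (camera adjusted p = 0.057); NQO1 and SLC7A11 stood at -1.94 (SE 0.10) and -1.74 (SE 0.12). Of 29 measured hypoxia and glycolysis genes 14 fell, 6 rose and 9 did not pass (camera adjusted p = 0.217), with EGLN3 and NDRG1 up by 1.90 (SE 0.24) and 1.51 (SE 0.19). Counts of these 4 lists were the same adjusted over the list alone.

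Of 13 measured mitochondrially encoded genes 11 rose, 0 fell and 2 did not pass, the same adjusted over the list alone, with MT-ND5 and MT-ND6 highest at 0.71 (SE 0.07) and 0.68 (SE 0.08). Mitochondrial rows held 6.46% to 7.37% of reads in untreated libraries and 8.11% to 8.46% in FIR libraries. Camera called that list higher (adjusted p = 0.0030), not kept with an estimated correlation (adjusted p = 0.327 with an estimated correlation). Of 56 measured cytosolic ribosomal protein genes 15 fell, 3 rose and 38 did not pass, and 13 fell and 2 rose adjusted over the list alone (camera adjusted p = 0.079); RPL10 and RPSA each fell by 0.45 (SE 0.08 and 0.07). Of 27 measured immediate early and heat shock genes 10 rose, 4 fell and 13 did not pass, the same adjusted over the list alone (camera adjusted p = 0.159), with KLF6 4.61 times and FOS 3.03 times higher (SE 0.11 and 0.42 on the log2 scale).

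Lineage lists were mixed. Of 32 measured epithelial luminal genes 15 rose, 4 fell and 13 did not pass (camera adjusted p = 0.057), led by OVOL1 and CD24 at 1.43 (SE 0.14) and 1.35 (SE 0.26). Of 12 measured basal cell markers 8 rose, 1 fell and 3 did not pass, led by COL17A1 and TRIM29 at 2.69 (SE 0.45) and 1.78 (SE 0.29). The basal list was higher by camera (adjusted p = 0.040), not kept with an estimated correlation (adjusted p = 0.221 with an estimated correlation), without FIR_40Gy replicate 2 (adjusted p = 0.064) or with a filter of 1 CPM in 3 libraries (adjusted p = 0.062). Of 24 measured mesenchymal genes 8 rose, 4 fell and 12 did not pass, and 5 fell adjusted over the list alone (camera adjusted p = 0.156); COL3A1 rose by 3.46 (SE 0.34) and VIM, vimentin, by 2.71 (SE 0.16). Of 15 measured stemness-associated genes 9 rose, 3 fell and 3 did not pass (camera adjusted p = 0.057). SALL4 had 2 reads over the untreated group and 95 over the FIR group, a ratio of 57.6 with a 95% counting interval of 15.5 to 483, and TERT, the telomerase reverse transcriptase, fell by 5.06 (SE 0.36). Counts of the luminal, basal and stemness lists were the same adjusted over the list alone.

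Markers of other cell types were few. None of 23 immune cell markers had a row. Of 7 measured fibroblast and smooth muscle markers 4 rose, 1 fell and 2 did not pass, and 5 rose adjusted over the list alone (camera adjusted p = 0.079); COL3A1 went from 0.401 to 4.47 CPM and COL1A1 fell by 2.17 (SE 0.17), from 24.0 to 5.33 CPM. Of 3 measured endothelial markers, too few for camera, VWF fell by 2.65 (SE 0.16) and 2 did not pass, the same adjusted over the list alone.

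**Figure D3:**
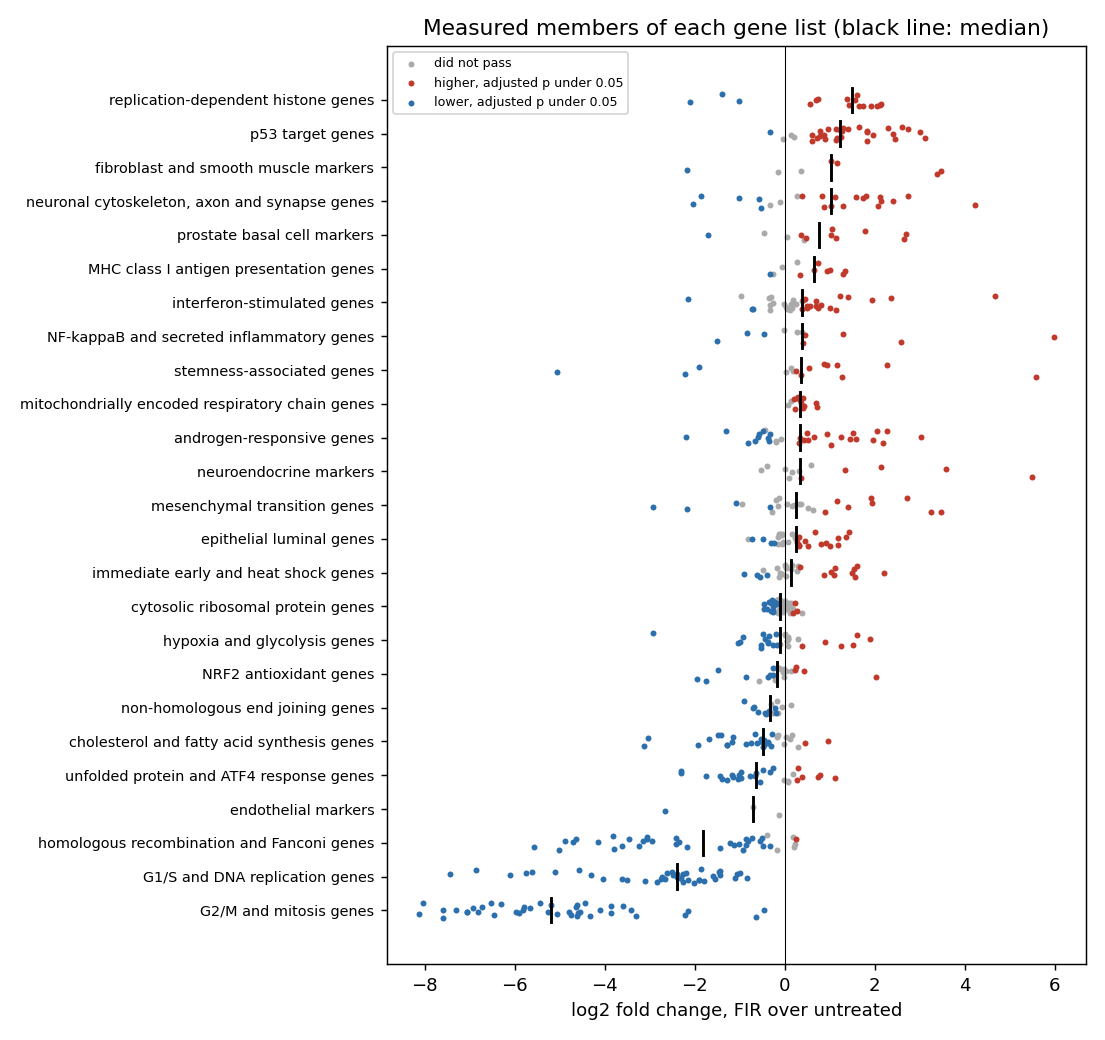
Each point is a measured member of a gene list with its log2 fold change, FIR over untreated; red rose, blue fell, grey did not pass, and the black line is the list median. All points of the mitosis list lie below 0 around a median of -5.19, and the p53 list has a median of 1.24.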

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

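Summing rows that share a symbol was chosen after seeing the data. Counts of higher and lower genes stayed within 1.5 times of 4136 and 3811 in each scaling, tool, filter and left-out library tried, from 3401 to 4162 higher and from 3368 to 4346 lower. The no-filter setting removed and added no gene and says nothing. Library-size scaling gave 3685 higher and 4346 lower. With the replicate number as a replicate block, 3988 genes were higher and 3668 lower. The deviations of same-numbered libraries correlated at 0.03, -0.05 and -0.07, so no effect shared by a number was seen. These values cannot show whether the cultures were handled in pairs, which the labels do not give. With an estimated correlation 0 lists were higher and 0 lower. The cause was not tested, and calls were lost also where that correlation was below 0, as in the neuroendocrine markers (-0.0411). The mitosis list, where all 41 measured genes fell, lost its call too, so this loss does not set 1 list apart from another. Fry, also planned, asks only whether a list's own genes changed. It gave adjusted p = 9.5e-05 for the mitosis list (lower) and 1.0e-04 for the p53 list (higher). The androgen-responsive list, which camera did not call, passed fry too (adjusted p = 0.038). Leaving out 1 library gave 4 to 9 higher lists, with 4 without FIR_40Gy replicate 2; the cause was not tested. The alternatives were run on the lists and on the 63 genes taken by the rule set in advance, and none of these reversed a call; other genes named in the text were not run. REST lost its call in 10 of 15 settings, and ENO2 gained one without untreated replicate 3. With a filter of 1 CPM in 3 libraries the neuroendocrine and basal lists lost their calls (adjusted p = 0.063 and 0.062). Calls were gained without 1 library by the MHC class I list (untreated replicate 3 and FIR_40Gy replicates 1 and 3, adjusted p = 0.030 to 0.044), luminal list (FIR_40Gy replicate 1, adjusted p = 0.038), stemness list (untreated replicate 1, adjusted p = 0.0498), NRF2 list (FIR_40Gy replicate 3, adjusted p = 0.044), ribosomal protein list (untreated replicate 2, adjusted p = 0.021) and fibroblast list (untreated replicate 3, adjusted p = 0.047). Under library-size scaling the MHC class I, stemness, NRF2 and ribosomal protein lists gained calls, under the filter the luminal, stemness and NRF2 lists, and under the block the stemness list. Depth limits genes with few reads in a group, such as KCNC2 with 3 in untreated cells, whose ratio of 248 has a counting interval of 84.6 to 1207.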

Other observations

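Of the tests in this part, the scans, the minimum of 3 RNAs at 5 CPM for RNAs without poly(A) tails, the repeat on REST targets outside the lists, the use of its spread in reading the histone rho and the choice of genes below came after values were seen; the other tests were set before. Among genes outside the lists, the immune checkpoint ligand CD274 was 10.1 times higher (5.23 ± 1.92 to 52.5 ± 18.9 CPM, SD, n = 3), the opioid receptor OPRK1 22.3 times, the glycoprotein GPNMB 16.9 times and the nitric oxide synthase NOS3 14.7 times, with adjusted p-values of 1.1e-07, 2.2e-08, 3.5e-10 and 5.0e-09 by edgeR. The interleukin antagonist IL1RN was 9.87 times, the tubulin TUBA1A 12.3 times and the actin-binding TMSB4X 9.36 times higher.

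A scan of 205 symbol stems with at least 8 protein-coding genes called 11 with camera. In the clustered protocadherins PCDHB, cell adhesion molecules of neurons, 14 of 15 genes rose and 1 did not pass (median 1.95, adjusted p = 4.9e-05), and in PCDHGA 9 of 12 rose and 3 did not pass (median 1.28, adjusted p = 2.6e-04). These are close paralogs, PCDHGA genes share exons, and their single values are uncertain. Nucleoporins (NUP) fell in 17 of 21 (median -0.64), the spindle complex HAUS in 7 of 8 (median -1.29) and mitochondrial ribosomal MRPL genes in 31 of 47 (median -0.35). No stem passed with an estimated correlation (smallest adjusted p = 0.723 with an estimated correlation). Of 298 windows of 10000000 bases 4 were called. On chromosome 2 from 130000001 to 140000000, rich in near-identical copies, 29 of 49 genes rose and 2 fell. On chromosome 4 from 90000001 to 100000000, 2 of 20 genes fell and 15 rose, among them BMPR1B, TSPAN5 and UNC5C at 2.48, 2.61 and 4.03. The others were chromosome 5 from 140000001 to 150000000 (49 of 98 rose, 12 fell) and chromosome 14 from 10000001 to 20000000 (11 of 15 rose, 0 fell). No window passed with an estimated correlation (smallest adjusted p = 0.961 with an estimated correlation).

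Of 16 measured histone genes 13 rose and 3 fell, while all 41 replication genes fell (adjusted p = 0.196 and 0.221 with an estimated correlation). Reads moving among the 38 measured histone rows are argued against as the whole cause, since their summed CPM was 2.42 times higher, 604 ± 6.74 against 1463 ± 56.4 (SD, n = 3). Reads lost to multiple mapping before counting, or shared with copies that have no row, are not covered by that sum. A different recovery of RNA without poly(A) tails stays open: the median of 43 such RNAs was -0.36 (95% interval -0.44 to -0.03), which meets the bound set in advance against it, an interval below 0.5. The bound is not used here, because 41 of the 43 lie under 5 CPM and the other 2 differ, RN7SL1 at 2.51 (adjusted p = 1.9e-05 by edgeR) and SNORD104 at -0.43 (adjusted p = 0.080, not passed); of all 43, 5 rose, 7 fell and the others did not pass. The hypothesis of longer, polyadenylated histone transcripts in arrested cells cannot be told apart from it: over the 38 histone rows the Spearman rho of fold change with length was -0.0030 (permutation p = 0.987), which meets the bound below 0 set in advance against it, but by less than its spread, since the bootstrap 95% interval, used in place of the permutation interval named in advance, was -0.32 to 0.31 and reaches past the 0.3 the hypothesis needs.

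Of 23 measured neuronal genes 15 rose, 5 fell and 3 did not pass (adjusted p = 0.226 with an estimated correlation), while ENO2 and SYP did not pass; depth as the reason is argued against for a 2-fold rise of those 2, since the higher of their upper 95% bounds was 0.74. Gene length is argued against by a neuronal median of 0.88 after the length trend was removed (1.02 before), and a mixture with cells of another line was not weighed here. Loss of repression by REST is a candidate explanation, as a hypothesis: 26 measured targets had a median of 0.65 (95% interval 0.21 to 0.81). For these targets limma's camera gave an adjusted p = 0.0017, and adjusted p = 0.041 with an estimated correlation. The camera values of REST targets were adjusted over 2 sets only, these 26 and the 17 outside the lists. They cannot be set beside the list values, which were adjusted over 24 lists. Of the 26, 15 rose, 2 fell and the others did not pass. SYP is among those that did not pass, so the hypothesis does not account for SYP. As 24 of the 53 listed targets are also in the neuronal or neuroendocrine lists, the 17 measured targets outside them were tested too (median 0.63, 95% interval 0.14 to 0.74, adjusted p = 0.012, and adjusted p = 0.054 with an estimated correlation, which does not pass). REST transcript itself did not fall, and repression was not measured. REST represses neuronal genes, so its targets could also rise where neuronal genes rose for another reason. These values cannot tell such cases apart.

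Of 11 measured MHC class I genes 7 rose, and the HLA-B and HLA-C rows lie on alternate haplotype sequences. With rows summed by symbol, HLA-B was 1.90 times and HLA-C 1.76 times higher, and the lower of their 95% bounds was 0.60 on the log2 scale, which argues against a division of reads between rows as the whole cause. Reads lost to multiple mapping before counting stay open.

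The 6 libraries make 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 4136 higher, 3811 lower, 1406 at least 2 times higher and 1202 at least 2 times lower genes, each as large in 1 split, and the highest of the other splits was 0 for each. Each other split mixes the treatments in both groups, which puts the difference between treatments into the spread within groups. Their counts of 0 are therefore no support against chance. The real split gave 7 higher lists, where the highest other split also gave 7 and 2 splits gave as many, and 6 lower lists, where the highest other gave 7 and 4 splits gave as many. The other splits hold the treatments in unequal numbers on each side, so part of the FIR difference stays in their comparison. Equal list counts therefore cannot decide whether the list calls arose by chance.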
